A study of Mus musculus with 7 samples.

How the data were processed

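Single-cell RNA sequencing was done on cardiac CD45+ cells, the immune cells of the heart, from C57BL/6J mice after sham surgery or transverse aortic constriction (TAC), a narrowing of the aorta that makes the left ventricle pump against a raised pressure. The labels give 2 conditions, 2 time points (1 and 4 weeks) and 7 samples, with 1 sample for sham at 1 week and 2 for each of the other 3 groups. Libraries were made with the 10x Genomics Single Cell 3' v2 kit. The authors deposited 1 matrix per group with integer UMI counts per gene and cell barcode, that is, counts of unique molecular identifiers with no normalization. The submitters' notes name bcl2fastq, Cell Ranger, R 3.5.0, Seurat 2.3.3 and the mm10 build. The version of Cell Ranger and the step at which each tool was used are not given in the sources used here. Libraries of a pooled matrix were separated by the number that ends each barcode, and they are called library 1 and library 2 of their group. The files do not tie that number to the replicate letters of the labels. The labels do not say that samples came from separate animals, so every p-value measures the spread between these samples only.

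Barcodes were kept with at least 200 detected genes, at most 10% mitochondrial UMIs and under 10% haemoglobin UMIs. The haemoglobin limit, which took out 43 barcodes, was set after seeing the data. Of 18115 barcodes, 303 were lost to these filters. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold called 20 of 17812 barcodes (0.112%), so the barcodes with the highest scores were removed instead, at 0.8% per 1000 cells of the library. That step, also decided after seeing the data, removed 385 barcodes and left 17427 cells. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 gave 26 clusters, with no batch integration and seed 1. Each cluster took the name of the marker list with the highest mean log2 level over the mean of all clusters, with at least 3 markers at 25% of their highest cluster, and classes are written with the suffix "like". A cluster in which a list of another lineage also scored at least 1, with at least 3 such markers, stayed unnamed. This left 5 clusters with 2205 cells (12.65%) without a name. The files hold no Ighm, Ighd, Iglc2, Igha, Trac, Trbc1, Trbc2 or Mx2, so markers and lists were used without them. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9, matplotlib 3.10.9, R 4.3.3 and its package data.table (1.17.8).

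UMIs were summed per library and cell class, so that libraries and not cells were the replicates. Each class with at least 20 cells in every library was tested, with macrophage-like cells tested for all their comparisons although 1 library held 13 of them. Genes were tested with edgeR 4.0.16 (TMM factors, filterByExpr, quasi-likelihood F test, 2-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE given with a log2 fold change is its absolute value divided by the square root of the F statistic. It restates the test on the log2 scale and is no separate measure of precision. Comparisons at 1 time point were contrasts of 4 group means fitted to all 7 libraries, so that the group with 1 library was assumed to vary like the others. The comparison over both times used condition with time as a covariate. Class shares were tested with edgeR quasi-likelihood on cell counts per library, and with a 2-sided exact permutation test where both sides held 2 or more libraries. Levels are CPM, the UMI counts of a class sum scaled to the same total in every library, given as mean ± SD over libraries. Intervals are 95% and cover counting error only: exact Clopper-Pearson for shares of cells and exact Poisson for ratios of pooled counts. A group with 0 counts was set at a floor of 3 counts over the group. Library totals ran from 5489792 to 14630675 UMIs, and median UMIs per barcode from 1359.5 to 3388. Coordinates are those of GRCm38 in GENCODE M21, which held 27722 of the 27998 gene identifiers. Data were simulated with the same library sizes, 1 mean profile for all libraries and changes only in genes above 20 CPM. Lasting differences between libraries were left out, so rates in the real data can be lower. On these data, a 4-fold change was called for 78.8% of the changed macrophage-like genes at 1 week, 71.2% at 4 weeks and 95.5% with time as a covariate. A 2-fold change was called for 14.7%, 8.8% and 27.9%.

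The comparisons, tests, gene lists and 16 alternatives were fixed before the data were examined. The 24 lists were tissue-resident macrophage, recruited monocyte-derived macrophage, MHC class II antigen presentation, inflammatory cytokines and chemokines, NF-kB targets and regulators, type I interferon response, fibrosis-associated and lipid-associated macrophage, immediate-early and dissociation stress, cell cycle, hypoxia and glycolysis, oxidative phosphorylation, angiogenic and growth factors, phagocytosis and efferocytosis, complement, iron and heme handling, lysosome, T cell activation and checkpoint, regulatory T cell, naive T cell, effector and cytotoxic T or NK, B cell activation, neutrophil activation and ageing, neutrophil granule and early maturation, and ribosomal protein. Lists with at least 5 tested genes were tested with limma 3.58.1 (voom and camera, preset correlation 0.01, Benjamini-Hochberg over the lists), and with an estimated correlation and fry beside it. A sex-linked check of 5 genes was read in all cells. Named genes are the 12 largest called changes in each direction with at least 20 CPM (6 for the other contrasts, 4 in the other classes), leaving out predicted, ribosomal and mitochondrial genes. Added to these are up to 4 members of each list with the smallest p and a fixed set of macrophage, T cell and B cell genes. Where none was called, the 5 with the smallest p are named.

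Alternatives chosen before the values were seen were DESeq2 1.42.0, RLE factors, no filter on low counts, a stricter cell filter (at least 500 genes, at most 5% mitochondrial UMIs), Leiden resolution 2.0, doublets kept, a fit on the compared groups only, TMM factors over the classes, an estimated correlation and leaving out each library. The planned block on the replicate letter was not run, as nothing in the files used here ties cells to the letters. Chosen after seeing the data were a block on the barcode suffix, a fit on 5 libraries without the 2 that held few macrophage-like cells, a term for those 2 libraries, a term for a set of 3 libraries described in the results, and sums without the highest cell of each gene. The values of 1 gene of the lists are not reported here. No alignment, velocity or receptor sequence data were analysed here.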

Results

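Gene expression was measured as UMI counts in single cardiac CD45+ cells of mice after sham surgery or TAC, to describe the immune cells of the heart while pressure overload develops. Sham at 1 week was a single library with no replicate, and sham at 4 weeks, TAC at 1 week and TAC at 4 weeks had 2 libraries each. The 7 libraries held 18115 barcodes and 65431395 UMIs. The sham 1-week library had 10974610 UMIs. At 4 weeks, sham library 1 had 5836991 and sham library 2 had 11397514. TAC at 1 week had 5489792 UMIs in library 1 and 10541055 in library 2, and TAC at 4 weeks had 6560758 in library 1 and 14630675 in library 2. Between 1380 and 3106 cells per library entered the comparisons, 17427 in all.

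B cell-like, T cell-like, macrophage-like, monocyte-like and NK cell-like cells were the main named classes of the cardiac leukocytes. Macrophage-like clusters were led by C1qa, C1qb and C1qc (subunits of complement C1q) and Pf4, and the larger one also by Mrc1 (the mannose receptor). Monocyte-like clusters were led by Lyz2, Chil3 and F13a1, apart from 1 of 372 cells led by Ear2, Cd300e and Treml4. Macrophage-like cells made up 19.96% of the sham 1-week library and 24.9% and 15.3% of the TAC 1-week libraries. At 4 weeks they made up 13.1% of sham library 2 and 10.96% of TAC library 2, but 13 cells or 0.419% (exact 95% interval 0.223 to 0.715%) of sham library 1 and 31 cells or 1.67% (1.14 to 2.36%) of TAC library 1. Those last 2 libraries also held the most neutrophil-like cells, 5.12% and 12.5%, against at most 0.58% in the other 5. No innate lymphoid type 2 or mast or basophil-like cell was seen in TAC 4-week library 1, which allows up to 0.161% of each by 3 counts of the total and 0.198% by the exact 95% interval.

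**Figure D1:**
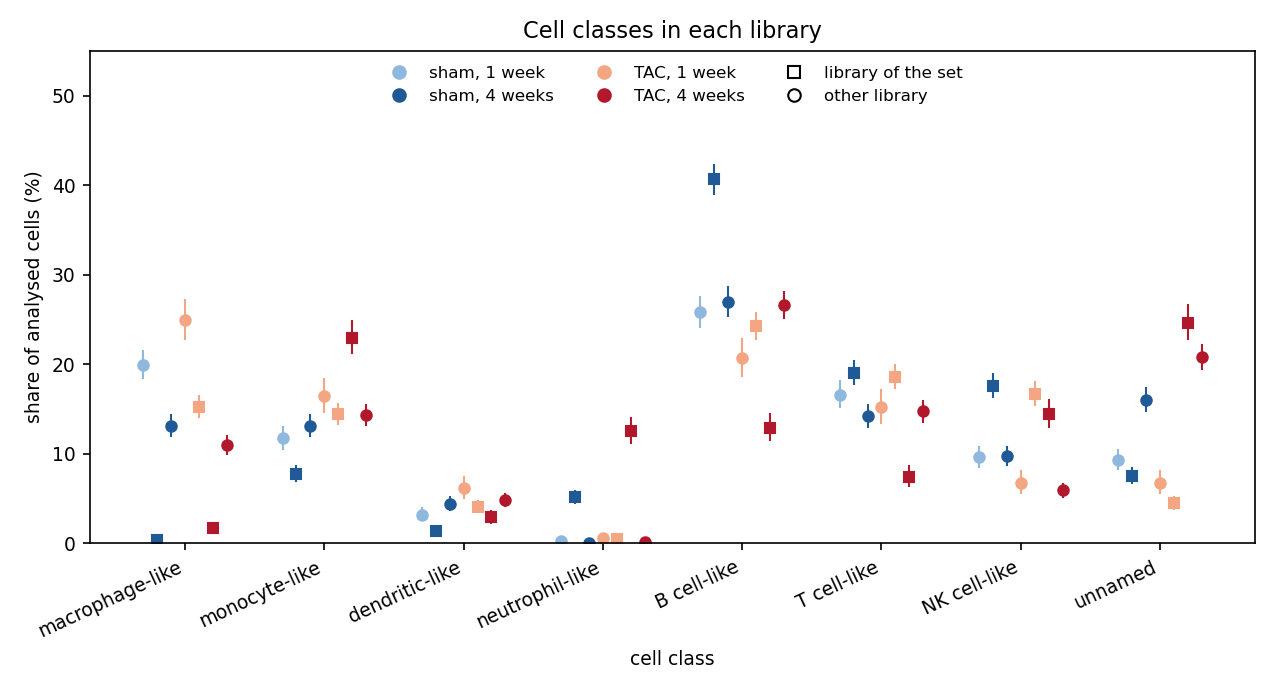
Share of analysed cells (%) in 8 cell classes for each of the 7 libraries, with exact 95% binomial intervals as bars and color for group; squares mark the set of 3 libraries described in the text. Macrophage-like cells lie at 0.419% and 1.67% in 1 sham and 1 TAC library at 4 weeks and between 10.96% and 24.9% in the other 5.

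A set of 3 libraries, 1 from each replicated group, stood apart in all 6 tested classes by a group of genes that includes Arf5 (vesicle transport), Iscu (iron-sulfur cluster assembly), Ypel3 and Sys1. Over all cells, Arf5 was 317, 171 and 429 CPM in sham 4-week library 1, TAC 1-week library 2 and TAC 4-week library 1, against 50.8 to 68.9 CPM in the other 4. Scand1 was 257, 19.6 and 332 CPM in the same 3 libraries and at most 1.8 CPM elsewhere. The set differed from the other 4 libraries in 257 macrophage-like genes (156 higher, 101 lower) and in 206 to 585 genes of the other classes (edgeR quasi-likelihood, adjusted p under 0.05, chosen after seeing the data). As the set holds both conditions and both times, the counts of genes and lists for TAC against sham below are also given with the set as a covariate, and no class share passed with it. Arf5 and Scand1 were lower in the 1-week library of the set than in its 4-week libraries, while the covariate takes the set as equal in all 3. Sham at 1 week holds no library of the set. Fits with the set as a covariate can therefore leave or add differences of the set. The sex-linked check gave 0 to 3 Xist UMIs per library and at least 455 Ddx3y, 475 Eif2s3y, 49 Uty and 41 Kdm5d UMIs in each of the 7 libraries.

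**Figure D2:**
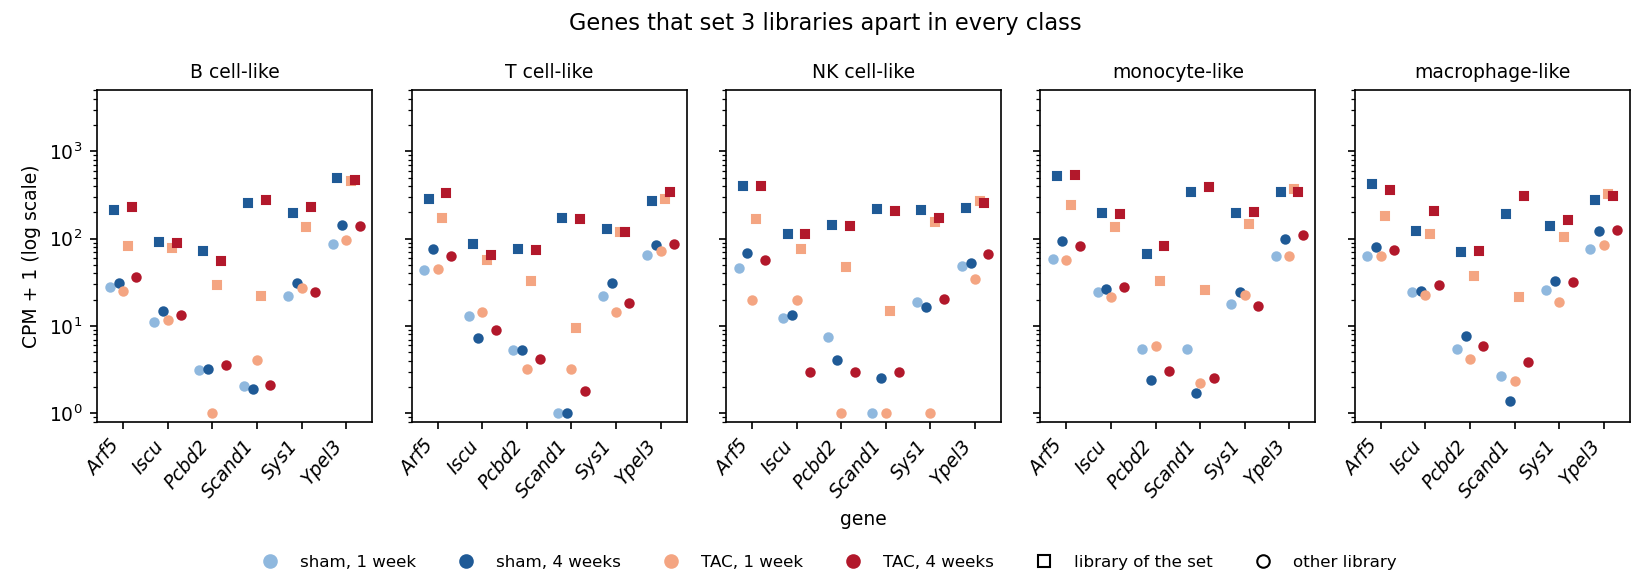
Level of Arf5, Iscu, Pcbd2, Scand1, Sys1 and Ypel3 (CPM + 1, log axis) in 5 cell classes of each library, with color for group; squares are the 3 libraries of the set and circles the other 4. The squares lie above the circles, as for Arf5 over all cells at 171 to 429 against 50.8 to 68.9 CPM.

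At 1 week, the comparison of TAC with sham asks how early pressure overload changes cardiac immune cells. Macrophage-like cells of TAC hearts had higher levels of the list of fibrosis-associated and lipid-associated macrophage genes, of type I interferon-stimulated genes, of lysosomal genes and of recruited monocyte-derived macrophage genes by camera at a preset correlation. With an estimated correlation none of these lists passed (adjusted p = 0.565), and the interferon list did not pass with the library set as a covariate (0.0588). Among single genes, positive log2 fold changes that did not pass were those of Spp1 (osteopontin), Arg1 (arginase 1), Timp1 (a protease inhibitor) and Mmp14 (a membrane protease), and negative ones those of Retnla and Vsig4 (a complement receptor of resident macrophages). Jchain, the joining chain of plasma cell antibodies (ENSMUSG00000067149, chromosome 5, 88519809 to 88527891), was the 1 gene of 10645 that passed. Its log2 fold change was -4.38 (SE 0.62, adjusted p = 4.44e-05), at 224 CPM in the sham library and 22.4 and 0 CPM in both TAC libraries, a ratio of pooled counts of 0.0448 (0.033 to 0.0596). A single cell held 591 of the 819 Jchain UMIs of the sham library (72.2%).

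The fibrosis-associated and lipid-associated list rose (14 of 17 genes higher, median log2 0.50, camera adjusted p = 3.45e-05; adjusted p = 0.565 with an estimated correlation). None of its genes passed over all genes and 4 passed when adjusted over the list alone. Spp1 had a log2 fold change of 2.55 (SE 0.61, adjusted p = 0.290), with 29.9 CPM in sham and 43.6 and 313 CPM in TAC. Arg1 had 2.53 (SE 0.66, adjusted p = 0.584), Mmp14 2.50 and Timp1 3.91, the last at 0.274 CPM in sham and 4.94 and 5.1 CPM in TAC. Trem2, a lipid receptor of macrophages, had 0.93, and Apoe, a lipid carrier, 0.43. All 18 tested interferon genes were higher (median 0.41, adjusted p = 7.94e-05, and 0.565 with an estimated correlation), among them Ifit3 (1.04), Ifi47 (1.06) and Oas1a (1.27). The lysosome list rose with 17 of 20 genes higher (median 0.30, adjusted p = 7.94e-05, and 0.565), with Ctsd (cathepsin D) at 0.71 and Naglu at 1.43. Recruited macrophage genes rose with 14 of 15 higher (median 0.26, adjusted p = 0.00137, and 0.565), with Ms4a7 at 1.20, Fn1 (fibronectin) at 1.02, Chil3 at 0.80 and Ccr2, the monocyte chemokine receptor, at 0.69.

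Lists of effector and cytotoxic lymphocyte genes (median 0.53, adjusted p = 0.00445), hypoxia and glycolysis (0.25, 0.0308) and oxidative phosphorylation (0.15, 0.0427) also rose in these macrophage-like sums. Naive T cell genes fell (10 of 10 lower, median -0.48, adjusted p = 0.000164), with Lef1 at -0.94 and Tcf7 at -1.01. Ribosomal protein genes (median -0.12, adjusted p = 0.00524), immediate-early and dissociation stress genes (-0.22, 0.0449, with Hspa1b at -1.28 the 1 gene adjusted over the list alone) and neutrophil granule genes (-0.53, 0.0471) fell as well. With an estimated correlation these 7 lists had adjusted p between 0.565 and 0.619. The effector and naive T cell lists are of lymphocyte genes, and carry-over of lymphocyte RNA or cells was not tested for them. The effector list had a mean log2 of CPM + 1 of 5.07 in TAC library 2, where 16.7% of cells were NK cell-like. It had 4.40 in TAC library 1 (6.74%) and 4.27 in sham (9.61%). The tissue-resident list did not pass (10 of 14 lower, adjusted p = 0.0698), with Vsig4 at -1.75 (SE 0.51), the 1 gene adjusted over the list alone, Timd4 at -0.80, Cd163 at -0.70, Lyve1 at -0.44 and Mrc1 at -0.18. The cytokines Osm (0.71), Il1b (0.54) and Tgfb1 (0.29), Tnf (-0.10), Hif1a (0.04) and Igf1 did not pass either. With the library set as a covariate the interferon list no longer passed (adjusted p = 0.0588), nor did the effector (0.11), ribosomal (0.272), hypoxia (0.375), oxidative phosphorylation (0.229) and stress lists (0.0836). The MHC class II (0.00185), cell cycle (0.00212), complement (0.0178) and B cell activation lists (0.0113) then passed on the higher side, so that 9 lists passed in place of 11. The set fit was run at the preset correlation only, and without the set no list passed with an estimated one.

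Among other cells at 1 week, T cell-like sums had less Jchain in TAC (log2 -8.09, adjusted p = 0.0106), where 1 cell held 98.1% of the 208 UMIs of the sham library and both TAC libraries lay below it. Cell cycle genes fell in NK cell-like cells (16 of 19 lower, median -0.87, adjusted p = 3.06e-09; adjusted p = 0.854 with an estimated correlation), with Ube2c at -4.05, Ccnb2 at -3.72 and Birc5 at -2.13, the 3 that passed adjusted over the list alone. This class includes a cluster of 68 cells led by such genes, among them Stmn1, Birc5, Ube2c and Ccnb2. It held 9 of 224 NK cell-like cells in sham, and 3 of 93 and 13 of 502 in TAC, so the fall can rest on few cells. Interferon genes rose in monocyte-like cells (15 of 18 higher, median 0.32, adjusted p = 0.00254, and 0.83 with an estimated correlation) and recruited macrophage genes in dendritic-like cells (12 of 13, median 0.57, adjusted p = 0.000831, and 0.785). Effector genes rose in T cell-like cells (10 of 13, median 0.28, adjusted p = 0.0306) and MHC class II genes fell there (8 of 11, median -0.87, adjusted p = 0.000891), both at 0.689 with an estimated correlation. Pdcd1, the checkpoint receptor PD-1, was at 1.06 and Il17a at 0.28 in T cell-like cells and did not pass.

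In the counts at 1 week, edgeR quasi-likelihood called 1 macrophage-like gene (0 higher, 1 lower, with 180 at an unadjusted p under 0.05 and 0 by DESeq2) and 1 gene in the 5 other classes. The second count lies in T cell-like cells, while B (177 unadjusted, 0 by DESeq2), dendritic (136, 1), monocyte (155, 1) and NK cell-like cells (110, 0) had 0. Chance alone would give about 532 macrophage-like genes, and 333 to 455 genes in each other class, at an unadjusted p under 0.05. The unadjusted counts of genes given here and below all lie under these numbers, so they are no sign of further changes. With the set as a covariate, chosen after seeing the data, there were 2 macrophage-like genes, Jchain and Retnla (log2 -2.62, adjusted p = 2.82e-09, 120 CPM in sham, 29.2 and 4.37 in TAC), and 6 genes in other classes. The set term is shared by all groups, and the Retnla pairs at 4 weeks went opposite ways. The library of the set had 1330 against 331 CPM in sham and 0 against 207 CPM in TAC. With 1 sham library at 1 week, this small p-value should not be read as the spread of Retnla between libraries. The macrophage-like count was 0 without either sham 4-week library, 33 without TAC 1-week library 1, 11 without TAC 4-week library 1 and 12 without TAC 4-week library 2, and the 11 called lists became 2 without TAC 1-week library 2. No class share passed of 11 tested (edgeR quasi-likelihood, 0 at an unadjusted p under 0.05), with macrophage-like cells at 20.1% ± 6.84 (SD, n = 2) in TAC.

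**Figure D3:**
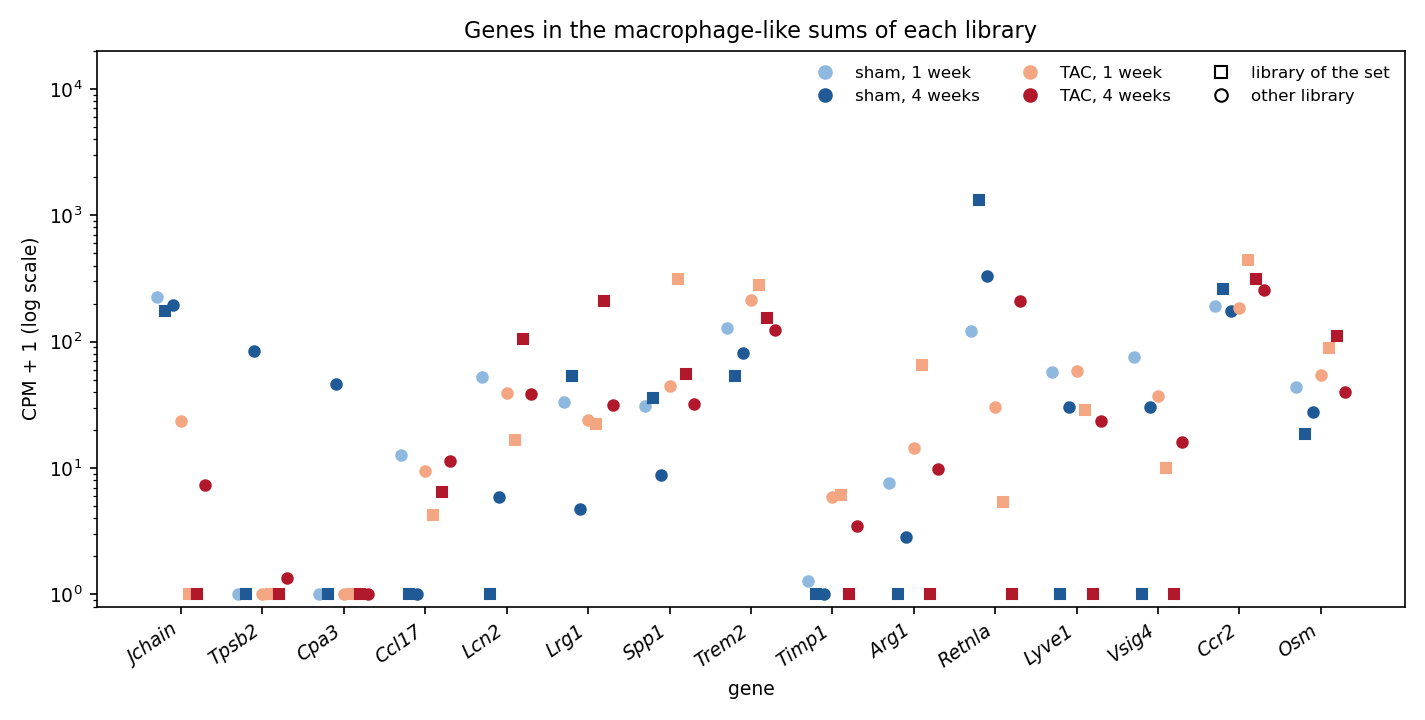
Level of 15 genes in macrophage-like sums (CPM + 1, log axis) for each of the 7 libraries, with color for group; squares are the 3 libraries of the set. Jchain lies at 174 to 224 CPM in the 3 sham libraries and at 0 to 22.4 CPM in the 4 TAC libraries, and Tpsb2 and Cpa3 are high in 1 sham library at 4 weeks.

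At 4 weeks, the question is how the cells differ once overload has lasted. Macrophage-like sums of TAC hearts had more Lcn2 (lipocalin 2, an iron-sequestering protein of neutrophil granules) and Lrg1 (a glycoprotein made by neutrophils and by inflamed tissue), and all 10 tested neutrophil granule genes were higher. Carry-over of neutrophil RNA or cells into these sums was not tested for Lcn2, Lrg1 or the granule genes. Genes of recruited macrophages and of fibrosis-associated macrophages were again higher, while MHC class II and cell cycle genes were lower, by camera at a preset correlation. No list passed with an estimated correlation (lowest adjusted p = 0.477). The mast cell proteases Tpsb2, Mcpt4, Cpa3 and Cma1, and Jchain, were higher in sham, where they came from few cells.

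Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) had a log2 fold change of 3.55 (SE 0.64, adjusted p = 0.00195), at 0 and 4.86 CPM in sham and 104 and 37.9 CPM in TAC. The ratio of pooled Lcn2 counts was 8.81 (4.97 to 17). The 0 CPM of sham library 1 comes from a sum of 57344 UMIs in 13 cells. The 104 CPM of TAC library 1 comes from 183375 UMIs in 31 cells. The Lcn2 call ended with DESeq2 (adjusted p = 0.807), at Leiden resolution 2.0 (0.0525), on 5 libraries (log2 2.97, 0.172) and without any 1 of the 3 sham libraries (0.0797 to 1). Lrg1 (ENSMUSG00000037095, chromosome 17, 56119678 to 56122001) had 3.95 (SE 0.76, adjusted p = 0.00617) and a ratio of 8.67 (4.89 to 16.7). Its level was 207 and 30.4 CPM in TAC and 3.74 CPM in sham library 2, while 3 UMIs made 52.3 CPM in sham library 1. Without sham library 2 the log2 fold change of Lrg1 was 0.90 and without TAC library 1 it was 2.49, and Lrg1 was called in neither fit. The Lrg1 call also ended with DESeq2 (log2 2.54), without the sham 1-week library (3.985, adjusted p = 0.226) and without sham library 1 (4.52). Ccl17, a chemokine of dendritic cells, was named after its values were seen: 7.28 (SE 1.58, adjusted p = 0.0373), with no UMI in sham, at least 9.08-fold higher in TAC by a floor of 3 counts over the group, and 28 of the 29 UMIs of TAC library 2 in 1 cell. The Ccl17 call ended with RLE factors (adjusted p = 0.0562), at Leiden resolution 2.0 (log2 4.40, 0.476) and with doublets kept (log2 4.56, 0.107). It also ended in fits without single libraries. The neutrophil granule list rose (median 1.39, adjusted p = 3.24e-14; adjusted p = 0.477 with an estimated correlation), with 1 gene passing over all genes and 5 adjusted over the list alone. Among these, Chil3 had 1.61 (adjusted p = 0.302), Retnlg 1.57 (0.302) and Wfdc21 1.88 (0.497). Neutrophil-like cells were 12.5% of TAC library 1 and 5.12% of sham library 1, against 0.195% and 0.038% in the libraries 2. The list of neutrophil activation rose too (11 of 15 higher, median 0.24, adjusted p = 0.018, and 0.549 with an estimated correlation).

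Recruited macrophage genes rose (14 of 15 higher, median 0.62, adjusted p = 4.34e-07; adjusted p = 0.477 with an estimated correlation), and 6 passed adjusted over the list alone. They were Il1b (log2 0.88), Chil3, Plac8, Hp (haptoglobin, 1.44) and Ly6c2 (1.03), which were higher, and Lyz1 (-1.63), which was lower. All 17 fibrosis-associated genes were higher (median 0.80, adjusted p = 8.81e-06, and 0.477), with Spp1 at 1.99, Mmp12 (an elastase of macrophages) at 2.297 and Lgals3 (galectin 3) at 0.87, of which Spp1 and Mmp12 passed adjusted over the list alone. Interferon genes rose (16 of 18, median 0.52, adjusted p = 0.000175, and 0.579), with Oasl2 at 1.76, Isg15 at 1.15, Rtp4 at 1.07 and Ifit3 at 0.99. MHC class II genes fell (12 of 13 lower, median -0.44, adjusted p = 1.98e-05, and 0.477), with H2-Ab1 at -0.55 and H2-Eb1 at -0.57. Cell cycle genes fell (14 of 17, median -0.36, adjusted p = 0.000175, and 0.565), with Mki67 at -2.70, Ccnb2 at -2.21 and Birc5 at -1.93. Lysosome (0.25, 0.00558), hypoxia (0.31, 0.0081) and oxidative phosphorylation lists (0.18, 0.0335) rose and the ribosomal (-0.19, 0.00543) and regulatory T cell lists (-0.33, 0.0383) fell, with adjusted p of 0.477 to 0.602 by an estimated correlation. The regulatory T cell list is of lymphocyte genes, with the limit given for 1 week. In the fit on 5 libraries, chosen after seeing the data, 4 of these 12 lists passed, the neutrophil granule, recruited, MHC class II and cell cycle lists. The fibrosis-associated (adjusted p = 0.0522), interferon (0.0639) and other 6 lists (0.16 to 0.959) did not. With the library set as a covariate 11 passed, without oxidative phosphorylation (0.0587). Trem2 (0.84), Arg1 (2.06), Timp1 (5.21), Osm (1.18), Ccr2 (0.50), Tgfb1 (0.99), Ccl2 (-0.78), Lyve1 (-0.52), Timd4 (-0.77), Cd163 (-0.55), Mrc1 (-0.26), Tnf (0.24), Igf1 (0.20) and Il10 (-2.23) did not pass over all genes. Timp1 was 0 CPM in both sham libraries and 0 and 2.48 CPM in TAC, so its 5.21 is a model value against a group with no count.

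Of the 5 genes lower in TAC at 4 weeks, Tpsb2 (ENSMUSG00000033825, chromosome 17, 25366305 to 25369098) had a log2 fold change of -7.43 (adjusted p = 1.46e-06) and a ratio of pooled counts of 0.00404 (0.000102 to 0.0227). Mcpt4 (ENSMUSG00000061068, chromosome 14, 56059629 to 56062313; adjusted p = 4.85e-06) had a ratio of 0.00586 (0.000147 to 0.0331), with 1 UMI in TAC. Cpa3 (ENSMUSG00000001865, chromosome 3, 20215620 to 20242181; adjusted p = 6.41e-06) was at least 44.8-fold lower, and Cma1 (ENSMUSG00000022225, chromosome 14, 55941451 to 55944675; log2 -2.56, adjusted p = 0.00725) had a ratio of 0.14 (0.0979 to 0.196). All 4 were high in sham library 2 and not in sham library 1, and 1 cell of that library held 74.7%, 83.2%, 92.6% and 69% of their UMIs. Jchain had -4.98 (adjusted p = 2.24e-05), at 174 and 194 CPM in sham and 0 and 6.37 CPM in TAC, with 48.3% of the UMIs of sham library 2 in 1 cell.

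In dendritic-like cells Ifitm1, an interferon-induced membrane protein (ENSMUSG00000025491, chromosome 7, 140967221 to 140969825), rose at 4 weeks. Its level was 342 ± 6.89 CPM (SD, n = 2) in TAC and 45.0 ± 11.6 CPM (n = 2) in sham, with log2 2.82 (SE 0.27, adjusted p = 0.0114) and a ratio of pooled counts of 6.83 (4.99 to 9.56). The Ifitm1 call ended without sham library 1 (adjusted p = 0.142), sham library 2 (0.272) or TAC library 2 (0.104), at log2 values of 2.65, 3.14 and 2.76, and also in the fit of the compared groups only (2.80, 0.233) and on 5 libraries (2.68, 0.0502). Effector and cytotoxic genes rose in T cell-like cells (12 of 13 higher, median 0.45, adjusted p = 2.26e-06; adjusted p = 0.574 with an estimated correlation), with Il17a at 2.75 and Fasl at 1.76 passing adjusted over the list alone, and Pdcd1 at 1.26. The class differed in make-up between libraries, since a T cell-like cluster led by Igfbp4, Lef1 and Dapl1 held 82.2% of it in sham library 1, 51.4% in TAC library 1 and at most 1.8% in the other 5. In NK cell-like cells 9 lists passed (8 higher, 1 lower, adjusted p = 0.559 with an estimated correlation). Among these the complement list had C1qa at 3.95 and C1qc at 3.08, genes of macrophages, and the effector list fell (11 of 14 lower, median -0.26, adjusted p = 0.00409). Interferon genes rose in B cell-like cells (10 of 13, median 0.27, adjusted p = 0.0112, and 0.73), where 1 cluster held 98.3% of the class in sham library 1, 77.9% in TAC library 1 and at most 3.4% in the other 5.

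The 4-week counts from edgeR quasi-likelihood were 8 macrophage-like genes (3 higher, 5 lower; 162 at an unadjusted p under 0.05, 0 by DESeq2) and 1 gene in the other classes, in dendritic-like cells. B (68 unadjusted, 0 by DESeq2), monocyte (123, 0), NK (70, 0) and T cell-like cells (101, 0) had 0. With the library set as a covariate, chosen after seeing the data, 19 macrophage-like genes passed (11 higher, 8 lower), all 8 among them, and 7 in other classes. The added ones include Ifitm1 (log2 2.02, adjusted p = 1.88e-05), Chil3 (1.497, 0.00552), S100a8 (1.00, 0.0204) and S100a9 (1.05, 0.0124), granule proteins of neutrophils and monocytes, and Retnla (-2.70, 7.71e-12) and Cxcl13 (-3.54, 0.000307) on the lower side. Retnla was 1330 and 331 CPM in sham and 0 and 207 CPM in TAC, with all UMIs of sham library 1 in 1 cell. Its small p-value should not be read as its spread between libraries. Of the 19, 9 had over 50% of their UMIs in 1 cell of their highest library. The count of 8 became 1 (Jchain) without the sham 1-week library, 2 (Tpsb2 and Mcpt4) without sham 4-week library 1, 0 without sham 4-week library 2 and 48 without TAC 4-week library 2. Without TAC 4-week library 1 it was 9, with Lrg1 not among them, and the 12 called lists became 5. No class share passed of 11 (0 at an unadjusted p under 0.05), where the smallest exact 2-sided permutation p of 2 against 2 libraries is 0.333. Monocyte-like cells were 18.6% ± 6.14 in TAC and 10.5% ± 3.79 in sham (SD, n = 2 each).

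Over both times, with time as a covariate, the comparison of 4 TAC with 3 sham libraries asks what overload changes at either stage. Macrophage-like cells of TAC had more AA467197, the transcript also known as Nmes1 (65.2 ± 50.8 CPM, n = 4, against 5.22 ± 7.19 CPM, n = 3, SD). They had less Jchain (7.21 ± 10.6 against 197 ± 25.2 CPM), lower in 4 of 4 TAC libraries than in each sham library. The fibrosis-associated and lipid-associated, recruited macrophage, interferon and lysosome lists were higher in TAC by camera at a preset correlation, and none passed with an estimated correlation (adjusted p = 0.406). Trem2 was 191 ± 69.0 against 86.3 ± 37.5 CPM and Spp1 111 ± 135 against 24.2 ± 14.4 CPM. Dendritic-like cells had more Ifitm1, at 591 ± 289 against 87.0 ± 73.1 CPM, higher in 4 of 4 TAC libraries.

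AA467197 (ENSMUSG00000033213, chromosome 2, 122636986 to 122641191) had a log2 fold change of 2.82 (SE 0.48, adjusted p = 0.0308), with 3 of 4 TAC libraries above each sham library and TAC 4-week library 2 at 9.56 CPM against 13.4 CPM in the sham 1-week library. The AA467197 call ended with RLE factors (adjusted p = 0.0637), DESeq2 (0.0665), on 5 libraries (0.994) and without any 1 of the 3 sham libraries (0.175 to 0.9997), at log2 values of 2.67 to 3.15. AA467197 and Ccl17 are also among the 10 leading genes of a dendritic-like cluster of 25 cells with Ccl22 and Fscn1. Jchain had -4.64 (SE 0.57, adjusted p = 0.00119). Tpsb2 (-7.15, adjusted p = 0.00119), Mcpt4 (-5.88, 0.00189) and Cpa3 (-7.96, 0.00189) rested on sham 4-week library 2, where 1 cell held 74.7 to 92.6% of their UMIs. Ifitm1 in dendritic-like cells had 2.52 (SE 0.20, adjusted p = 0.000598), and Il1b there had 1670 ± 464 CPM in TAC and 692 ± 108 CPM in sham, which passed with the library set as a covariate (log2 1.08, adjusted p = 0.0254) and not without it (0.401).

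The fibrosis-associated and lipid-associated list rose over both times (16 of 17 genes higher, median log2 0.67, camera adjusted p = 1.15e-08; adjusted p = 0.406 with an estimated correlation). None of its genes passed over all genes and 8 did adjusted over the list alone, among them Timp1 (log2 4.16), Spp1 (2.35), Arg1 (2.43) and Trem2 (0.87). Timp1 was low throughout, at 0 to 0.274 CPM in sham and 0 to 5.1 CPM in TAC. Recruited macrophage genes rose (14 of 15, median 0.60, adjusted p = 1.44e-07, and 0.406), with Chil3 at 1.17 the 1 gene adjusted over the list alone, Il1b at 0.73 and Plac8 at 0.70. All 18 interferon genes were higher (median 0.46, adjusted p = 2.83e-07, and 0.406), with Ifit3 at 1.00, Oasl2 at 0.93 and Rtp4 at 0.78. Lysosome genes rose (18 of 20, median 0.27, adjusted p = 3.12e-06, and 0.406), with Ctsd at 0.52. Hypoxia and glycolysis (13 of 18 higher, median 0.22, adjusted p = 0.00125, and 0.406), oxidative phosphorylation (19 of 20, 0.15, 0.0035, and 0.541), neutrophil granule (7 of 10, 0.25, 0.00661, and 0.541) and effector lists (13 of 15, 0.22, 0.0183, and 0.541) rose. Ribosomal protein (19 of 20 lower, median -0.17, adjusted p = 0.000132, and 0.531) and naive T cell lists (10 of 10 lower, -0.35, 0.0035, and 0.531) fell. The effector and naive T cell lists are of lymphocyte genes, with the limit given for 1 week. With the set as a covariate the naive T cell (adjusted p = 0.124) and effector lists (0.341) did not pass and the complement (0.0171) and iron lists (0.0496) did, again 10 lists in all, and fry called 0 lists of macrophage-like cells in any of the 3 comparisons. In the other classes fry called 1, the NF-kB list in monocyte-like cells over both times (3 of 17 higher, median -0.18, fry adjusted p = 0.0368; camera adjusted p = 0.104).

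The other 14 lists did not pass over both times. Tissue-resident genes had a median log2 of -0.05 (adjusted p = 0.145), with Vsig4 at -1.46, the 1 gene adjusted over the list alone, Cd163 at -0.63, Timd4 at -0.79, Lyve1 at -0.47 and Mrc1 at -0.21. Complement genes had a median of 0.14 (adjusted p = 0.0585), MHC class II -0.22 (0.124), neutrophil activation 0.11 (0.124), inflammatory cytokines 0.17 (0.225), angiogenic factors 0.25 (0.368) and the cell cycle -0.05 (0.612). The median was above 0 and the test pointed down for immediate-early and stress genes (median 0.01, adjusted p = 0.612), NF-kB targets (0.02, 0.686), B cell activation (0.01, 0.837), phagocytosis (0.07, 0.909), T cell activation (0.09, 0.966) and regulatory T cell genes (0.14, 0.966). Of these, T cell activation (0.21) and B cell activation (0.001) had a mean above 0 and the other 4 below 0. Iron and heme handling had a median of 0.03 and a mean of -0.01, with the test up (0.944). Osm (0.87), Ccr2 (0.60), Tgfb1 (0.60), Tnf (0.02), Hif1a (0.13) and Igf1 (0.17) did not pass.

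**Figure D4:**
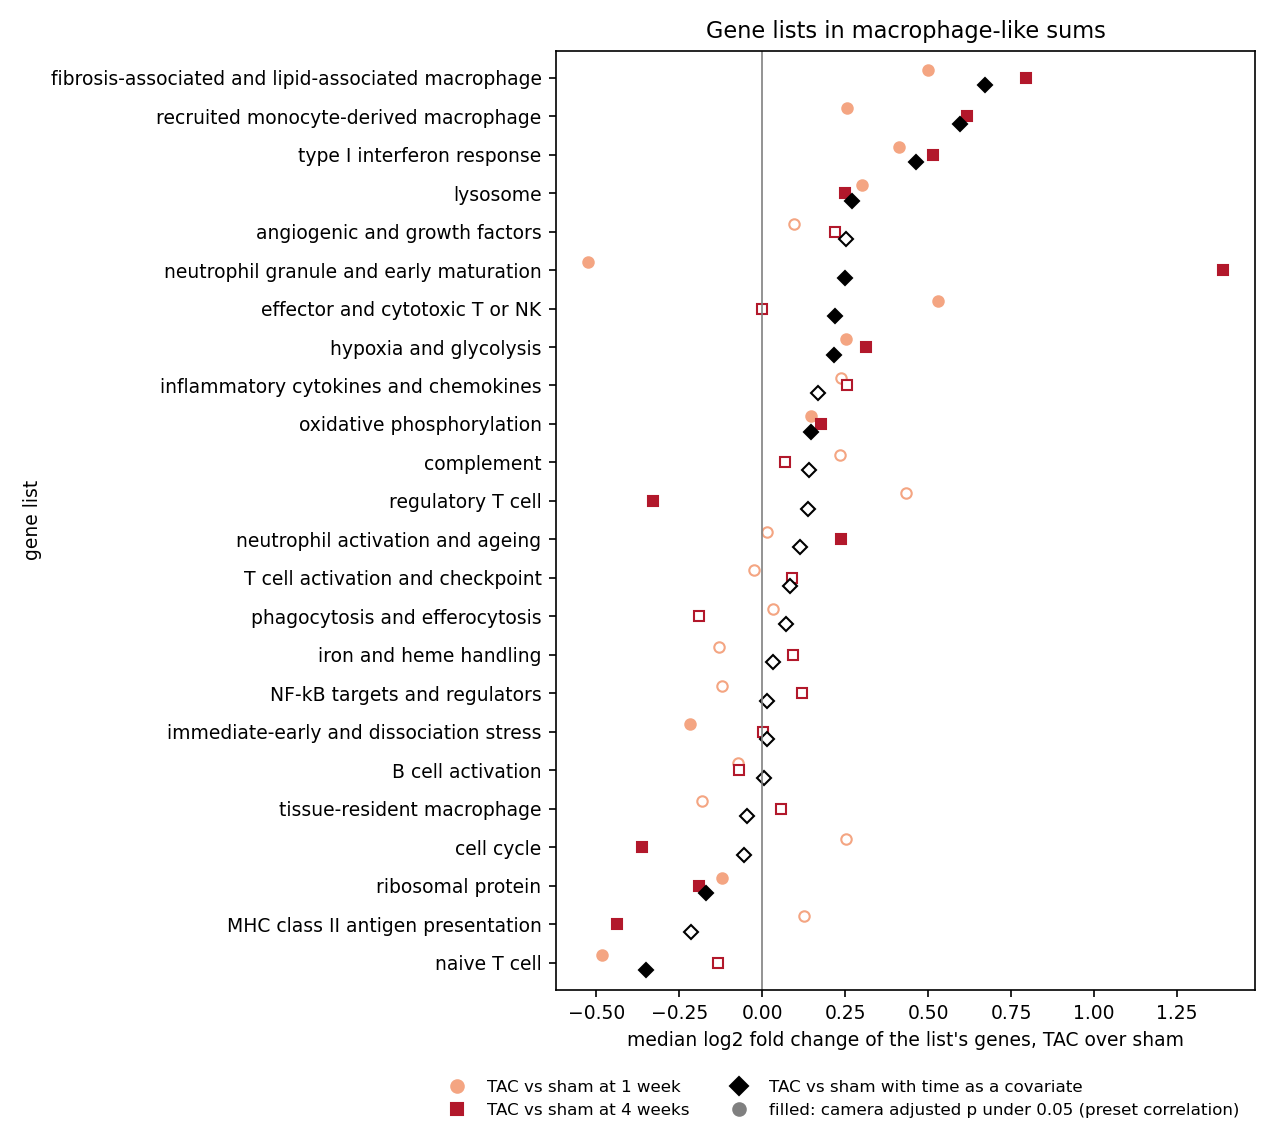
Median log2 fold change (TAC over sham) of each of the 24 gene lists in macrophage-like sums at 1 week (circles), at 4 weeks (squares) and with time as a covariate (diamonds), filled where the camera adjusted p is under 0.05. Fibrosis-associated genes lie at 0.50, 0.80 and 0.67, and neutrophil granule genes at -0.53, 1.39 and 0.25.

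Over both times edgeR quasi-likelihood called 5 macrophage-like genes (1 higher, 4 lower; 265 at an unadjusted p under 0.05, 0 by DESeq2) and 1 gene in the other classes, with B (131 unadjusted, 0 by DESeq2), monocyte (178, 0), NK (127, 0) and T cell-like cells (142, 0) at 0. The library set as a covariate, chosen after seeing the data, gave 25 macrophage-like genes (9 higher, 16 lower), all 5 among them. Higher were also Spp1 (log2 1.21, adjusted p = 0.00102), Timp1 (4.23, 0.0134), Arg1 (1.52, 0.0447), Apoe (0.70, 0.00545), Chil3 (1.08, 0.000156), Fabp5 (0.95, 0.00531), a fatty acid binding protein, and the chemokine Ccl8 (1.26, 0.0144). Timp1 was at most 0.274 CPM in sham and 5.1 CPM in TAC. Lower were Retnla (-2.45, 8.37e-32) and Mmp13, a collagenase (-1.26, 0.000256), both with all UMIs of their highest library, sham 4-week library 1, in 1 cell, and Cd207 (-1.14, 0.000731), Cxcl13 (-1.29, 0.0231) and Vsig4 (-0.98, 0.0447). Retnla overlapped between the conditions, at 120, 1330 and 331 CPM in sham and 29.2, 4.37, 0 and 207 CPM in TAC. Without the set it did not pass (adjusted p = 0.340). With this overlap, its small p-value should not be read as the spread of Retnla between libraries. Of the 25, 10 had over 50% of their UMIs in 1 cell of their highest library. The count of 5 became 1 without the sham 1-week library, 2 without either sham 4-week library, 46 without TAC 1-week library 1 and 13 without TAC 1-week library 2.

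Shares of classes over both times did not pass for any of 11 classes by edgeR quasi-likelihood (1 at an unadjusted p under 0.05). Monocyte-like cells made up 17.0% ± 4.09 (SD, n = 4) of TAC and 10.9% ± 2.78 (n = 3) of sham libraries, with an exact permutation p of 0.0571, the smallest that 4 against 3 libraries can give. These shares leave out an unnamed cluster of 313 cells with markers of B cells and monocytes, led by Ace, Ear2, Cd300e and Treml4. It held 4.28% of sham 4-week library 2 and 4.15% of TAC 4-week library 2, and at most 0.96% elsewhere. Counted as monocyte-like, it would lift sham 4-week library 2 (13.2%) above TAC 1-week library 2 (14.4%). The permutation p therefore depends on how that cluster is named. B cell-like cells were 21.1% ± 5.98 and 31.1% ± 8.25 (exact permutation p = 0.114). Macrophage-like cells were 13.2% ± 9.66 and 11.2% ± 9.91 (0.8 by exact permutation), and neutrophil-like cells 3.45% ± 6.06 and 1.79% ± 2.88 (0.686 by exact permutation). Endothelial-like cells had an unadjusted p of 0.0155 and an exact permutation p of 0.171. T cell genes of interest in T cell-like cells, Pdcd1 (1.16), Il17a (1.44), Ifng (-0.19), Ctla4 (0.11) and Icos (-0.11), did not pass, and Foxp3 was too low to test. Effector genes rose in T cell-like cells (11 of 13, median 0.31, adjusted p = 1.09e-06; adjusted p = 0.601 with an estimated correlation), with the difference in make-up given for 4 weeks. Recruited macrophage genes rose in dendritic-like cells (12 of 13, median 0.33, adjusted p = 0.000889, and 0.769), with Il1b and Plac8 adjusted over the list alone.

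Between TAC at 4 weeks and TAC at 1 week, the genes of macrophage-like cells with the smallest p were Retnla (log2 2.90) and Prg4 (3.38), higher at 4 weeks, and AA467197 (-2.42), Spp1 (-2.32) and Ccl7 (-1.71), a monocyte chemokine, lower at 4 weeks. These 5 did not pass (adjusted p from 0.0662 to 0.139), and edgeR quasi-likelihood called 0 genes (305 at an unadjusted p under 0.05, 0 by DESeq2). Retnla was 29.2 and 4.37 CPM at 1 week and 0 and 207 CPM at 4 weeks, and Prg4 was 0 and 18.8 CPM at 4 weeks, with 83% of the UMIs of library 2 in 1 cell. Spp1 was 43.6 and 313 CPM at 1 week and 54.5 and 31.2 CPM at 4 weeks. With the library set as a covariate, chosen after seeing the data, 31 genes passed (11 higher, 20 lower). The higher ones include Scand1 (log2 3.54, adjusted p = 4e-07), a gene that marks the set itself, at 20.4 CPM in its 1-week TAC library and 305 CPM in its 4-week one, so that the term left differences of the set in this comparison. The lower ones include the monocyte chemokines Ccl7 (-1.76, adjusted p = 3.03e-05) and Ccl2 (-1.19, 0.0117), and the macrophage genes Apoe (-0.93), Pf4 (-1.04), C1qa (-0.97), Lgmn (-1.18) and Ms4a7 (-1.32). The count of 0 became 15 without TAC 1-week library 1, 1 without TAC 1-week library 2, 9 without TAC 4-week library 1 and 27 without TAC 4-week library 2. The other 5 classes had 0 genes (121 to 188 unadjusted, DESeq2 not run) and no share passed (0 of 11 at an unadjusted p under 0.05).

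Between sham at 4 weeks and sham at 1 week, a check on time alone, 6 macrophage-like genes passed (3 higher, 3 lower; 205 unadjusted, 0 by DESeq2). Tpsb2 was at least 100-fold and Cpa3 at least 54.3-fold higher at 4 weeks by the floor of 3 counts over the group, and Mcpt4 had a ratio of 104 (28.2 to 863), all from sham library 2. Lcn2 (log2 -3.51, adjusted p = 0.00404, ratio 0.0919) and Hbb-bs, a haemoglobin chain (-4.25, 0.00517, ratio 0.0529), were lower at 4 weeks in sham library 2, while the 0 counts in the 13 cells of sham library 1 are too few to tell, and Ccl17 was at least 10.7-fold lower, with its 43 UMIs at 1 week in 1 cell. With the library set as a covariate 23 genes passed (5 higher, 18 lower), among them the heat shock genes Hspa1b and Hsph1 and the chemokines Ccl7 and Ccl12 on the lower side. The count of 6 became 2 without sham 4-week library 1, 0 without sham 4-week library 2, 14 without TAC 4-week library 1 and 15 without TAC 4-week library 2. In T cell-like cells Jchain was lower at 4 weeks (log2 -7.25, adjusted p = 0.0107), and no share passed (0 of 11 at an unadjusted p under 0.05).

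The difference of the TAC effect between the times passed for 3 macrophage-like genes, all with a larger effect at 4 weeks (118 unadjusted, 0 by DESeq2). They were Lcn2 (log2 difference 4.52, SE 0.78, adjusted p = 0.00535), Lrg1 (4.54, SE 0.93, 0.0431) and Ccl17 (8.32, SE 1.71, 0.0431). Lcn2 was 51.8 CPM in sham and 38.2 and 15.7 CPM in TAC at 1 week, so that the fitted TAC effect was below 0 then, without passing, and above 0 at 4 weeks. At 4 weeks Lcn2 was 0 and 4.86 CPM in sham and 104 and 37.9 CPM in TAC. Much of the difference thus lies in the fall of sham between the times (log2 -3.51). With the library set as a covariate 9 genes passed (8 higher, 1 lower), including S100a8 (2.15), S100a9 (2.16) and Ifitm1 (2.80). The count of 3 became 0 without either sham 4-week library or TAC 1-week library 2, with Lrg1 at 1.49 (adjusted p = 0.868) without sham 4-week library 2, and 7 without TAC 1-week library 1 and 8 without either TAC 4-week library.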

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

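The tests of single cells and of free RNA for the plasma and mast cell genes, and the margin on the digestion test, were chosen only after the result was seen. The TAC effect differed between 4 weeks and 1 week for 3 macrophage-like genes by a test of the difference itself: Lcn2 (4.52 on the log2 scale), Lrg1 (4.54) and Ccl17 (8.32). None of the 3 passed on 5 libraries, at Leiden resolution 2.0 or without either sham 4-week library or TAC 1-week library 2, and Lrg1 fell to 1.49 (adjusted p = 0.868) without sham 4-week library 2. Ccl17 had its 43 UMIs of sham at 1 week in 1 cell, no UMI in sham at 4 weeks, and 28 of the 29 UMIs of TAC 4-week library 2 in 1 cell. Jchain in T cell-like cells differed by 10.79 (SE 1.13, adjusted p = 0.0413), where 204 of the 208 UMIs of the sham 1-week library lay in 1 cell. Outside the named classes, a cluster with markers of neutrophils and monocytes was led by the granule genes Camp, Ngp and Ltf. It held 22.12% of TAC 4-week library 1, at most 2.32% of any sham library and 0.93% to 2.69% of the other 3 TAC libraries. Over all cells, Camp had 291 UMIs and Ltf 101 in TAC 4-week library 1. Both had 0 in sham 4-week library 1, which held 72 cells of the cluster. Camp and Ltf therefore do not mark all of its cells, and which cells carried them was not tested. A cluster with markers of NK and B cells held 2.37% of TAC 4-week library 2 at most 0.94% of any sham library and 0.1% to 0.32% of the other 3 TAC libraries. No group had the 4 samples that a test for single outlying samples needs.

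Plasma and mast cell genes (Jchain, Tpsb2, Mcpt4, Cpa3 and Cma1) were called lower in TAC than in sham macrophage-like sums at 4 weeks, with Jchain high in all 3 sham libraries and the other 4 in sham 4-week library 2 alone (Cma1 at 16.7 and 17.4 CPM in the other 2 and 13.1 to 26.2 CPM in TAC). The tables argue against free RNA in the droplets, since the median of the other 5 classes was 1.57% of the macrophage-like CPM, where an even background needs levels of the same order. A few cells of another type inside the class remain a candidate explanation: the highest single cell held 74.7% of the UMIs of a gene (median of the 5 genes). Without the highest cell of each gene, Jchain, Tpsb2 and Mcpt4 still passed at 4 weeks and Cma1 did not, while Cpa3 was too low to test. Whether TAC hearts have fewer such cells stays open, since the share of mast or basophil-like cells did not pass at 4 weeks (0.243% in TAC and 0.448% in sham, adjusted p = 0.920 by edgeR quasi-likelihood), and that of plasma cells was not tested.

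In 1 library of each 4-week group, macrophage-like cells were few (13 and 31 cells) and neutrophil-like cells many. Shallow sequencing is argued against, because C1qa, C1qb and C1qc together reached 82.8 and 252 CPM over all cells of these libraries, at most 20.59% of the lowest of the other 5. Another source or yield of the cells, such as a larger part from blood, may contribute: the naive T cell list in T cell-like sums lay above the other 5 libraries in both, by at least 0.357 (log2). Another digestion or handling cannot be told apart from this, since the stress list in B cell-like sums lay below the other 5 libraries by a margin of -0.049, small beside the range of those 5. Hspa1a and Fos were left out of that list, as their levels had been seen before. Over all cells, Hspa1a was 43.2 and 197 CPM in the 2 libraries against 401 to 1200 CPM in the other 5. Fos was 546 and 788 CPM against 1250 to 1900 CPM. Levels over all cells also depend on the mix of classes, so they do not decide it. The 2 libraries belong to different conditions, so the design gives no biological explanation, and none was tested.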

How the results depend on the processing

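The fits on 5 libraries, with a term for the library kind, with a term for the library set, with a block on the barcode suffix and without the highest cell of each gene were chosen only after the result was seen. The files do not tie cells to the replicate letters of the labels, so the planned replicate block was not run, and a replicate block on the barcode suffix took its place. Libraries of the same suffix deviated together between the 2 groups at 4 weeks (correlation over all cells of 0.504). They did not between TAC at 1 week and sham (-0.385) or TAC at 4 weeks (-0.258), so the suffix is not shown to mark a batch over all groups. This replicate block gave 4 macrophage-like genes at 1 week, 2 between TAC times and 0 for the difference between times, 0 genes of other classes at 1 week, and moved no other count, though its 4 genes between sham times share 0 with the main 6. Of 293 alternatives for counts, 195 stayed within 1.5 times the main count and 98 moved. Of 7160 alternatives for 465 single genes, 6903 stayed on the same side of the threshold, 135 gained a call, 122 lost it and 0 reversed a called value, while 137 of 6580 uncalled in both fits took the other sign. The cause was not tested unless named. DESeq2 gave 0 macrophage-like genes at 1 week, 0 at 4 weeks, 0 over both times, 0 between sham times and 0 for the difference between times, and 3 and 2 genes of other classes at 1 week and over both times. RLE factors gave 1 gene for the difference between times. With no filter on low counts, which tests more genes, there were 6 macrophage-like genes at 1 week, 17 at 4 weeks, 32 over both times, 13 between TAC times and 16 between sham times, and 113, 42 and 51 in other classes at 1 week, at 4 weeks and over both times. The stricter cell filter gave 2 at 1 week, 3 between TAC times, and 0 in other classes at 1 week, at 4 weeks and over both times, where the main dendritic-like cluster (611 cells) was left unnamed and Ifitm1 there and Jchain in T cell-like cells were not tested. Leiden resolution 2.0 gave 0 for the difference between times. With doublets kept there were 2 macrophage-like genes at 1 week, 2 between TAC times and 0 in other classes at 1 week. Fitting the compared groups only, which leaves fewer samples for the spread, gave 0 at 1 week and 15 and 0 in other classes at 1 and 4 weeks. An estimated correlation called 0 lists at 1 week, 0 at 4 weeks and 0 over both times. The 5 libraries gave 0 macrophage-like genes at 1 week, 5 at 4 weeks, 0 over both times, 3 between TAC times and 0 for the difference, 4 and 2 in other classes at 1 and 4 weeks, and 4 lists at 4 weeks. A term for the library kind gave 13, 15, 19, 22 and 11 macrophage-like genes at 1 week, at 4 weeks, between TAC times, between sham times and for the difference, and 7 and 7 in other classes at 1 and 4 weeks. A term for the library set gave 2, 19, 25, 31, 23 and 9 macrophage-like genes at 1 week, at 4 weeks, over both times, between TAC times, between sham times and for the difference, and 6, 7 and 3 in other classes at 1 week, at 4 weeks and over both times. Without the highest cell of each gene there were 5 at 1 week, 3 over both times, 23 between TAC times, 5 for the difference and 0 in other classes at 1 week. Leaving out each library in turn, macrophage-like counts ran from 0 to 33 at 1 week, 0 to 48 at 4 weeks, 1 to 46 over both times, 0 to 27 between TAC times, 0 to 15 between sham times and 0 to 8 for the difference. Those of other classes ran from 0 to 1 at 1 and 4 weeks and stayed at 1 over both times. Lists ran from 2 to 14 at 1 week, 5 to 14 at 4 weeks and 9 to 13 over both times, and shares stayed at 0. The comparisons with sham at 1 week could not be fitted without its 1 library. Depth limits macrophage-like values of sham and TAC 4-week library 1, with 13 and 31 cells.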

Other observations

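The counts of splits of the libraries were planned, and the fits and splits with the library set as a covariate and the fits on 5 libraries and without the highest cell of each gene were chosen only after the result was seen. Among the smaller classes, innate lymphoid type 2-like cells carried Areg (amphiregulin, a repair factor), Il1rl1 (the IL-33 receptor), Gata3 and Csf2, and made up 1.59% of the sham 1-week library and 0.725% and 0.366% of the TAC 1-week libraries, with 0.225% and 0.977% in sham and 0% and 0.973% in TAC at 4 weeks. Mast or basophil-like cells with Mcpt8, Cpa3, Fcer1a and Il6 made up 0.815% of the sham 1-week library and 1.30% and 1.06% of the TAC 1-week libraries, with 0.032% and 0.864% in sham and 0% and 0.486% in TAC at 4 weeks. A T cell-like cluster of 265 cells was led by Cd163l1, Il17a, Cxcr6 and Icos, genes of interleukin 17-producing T cells, and a B cell-like cluster of 525 cells by Jchain, Mzb1 and Zbtb32, genes of antibody-secreting or innate-like B cells. Plasmacytoid dendritic-like cells with Siglech and Ccr9 made up 0.161% to 0.858% of a library. Neutrophil-like cells were led by Retnlg, S100a8, S100a9, Lcn2 and Lrg1, and the last 2 were also higher in TAC macrophage-like sums at 4 weeks.

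In monocyte-like cells, the neutrophil granule list rose in TAC over both times (8 of 8 genes higher, median log2 0.53, camera adjusted p = 0.00239; adjusted p = 0.704 with an estimated correlation). TAC 4-week library 1 also held the most neutrophil-like cells (12.5%) and 22.12% of its cells in the mixed neutrophil and monocyte cluster, with S100a8 at 19300 CPM over all cells. In NK cell-like cells at 4 weeks, S100a8 (log2 2.33) and S100a9 (2.08) passed with the library set as a covariate and not without it, at 1480 and 1130 CPM in TAC library 1, where 1 cell held 49.3% and 43.9% of the UMIs. The B cell-like sum of TAC 1-week library 1 held the heart muscle genes Myl7, Sln, Nppa and Tnni3, with 97.1% to 100% of their UMIs in 1 cell. Macrophage-like cells fell into 2 clusters, and the one with fewer UMIs per cell held 27.3% of them in the sham 1-week library, 32.0% and 48.1% in the TAC 1-week libraries, and 18.3% and 15.4% in sham and TAC library 2 at 4 weeks, but 53.8% of 13 and 38.7% of 31 cells in sham and TAC library 1.

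The genes of the lipid-associated and recruited macrophage lists were higher in TAC macrophage-like sums, with a median log2 fold change of 0.632 over 31 genes. For the 5 libraries with enough cells, another mix of the 2 macrophage clusters is argued against. The median there was 0.263 and 0.683 within the clusters, where the whole class had 0.338. The part of the 0.632 that was lost without the other 2 libraries could not be tested this way, as they held 13 and 31 macrophage-like cells. A mix within the clusters was not tested. A single cell with high counts per gene and library is argued against as well, since the median stayed at 0.561 without the highest cell of each gene. Several high cells per gene would remain after this step and were not tested. Free RNA cannot be excluded: the same genes had medians of 0.206, 0.193 and 0.432 in B, T and NK cell-like sums, too few of them tested and too spread to decide. Chance cannot be excluded either, as the smaller camera p of the 2 lists was at or below the real 4.79e-10 in 2 of 34 splits of the libraries, the real one included (lowest other 3.2e-11), and with the library set as a covariate the median was 0.434, so that a change of macrophage state after TAC stays a hypothesis.

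For the counts over both times, chance cannot be excluded for macrophage-like genes, genes of the other classes or lists. Of the 34 splits into 4 and 3 libraries that could be fitted, the real one included, 13 called at least the real 5 macrophage-like genes (highest other 625), 15 at least the real 1 gene of the other classes (highest other 2331), and 13 at least the real 10 lists (highest other 14). For class shares the splits test nothing, as the real count is 0 and all 34 reach it (highest other 3). The split that called 625 and 2331 genes parts the set of 3 libraries from the other 4 and points to a structure of the samples. With the set as a covariate, 33 splits could be fitted, and chance cannot be excluded there either. Of these, 10 called at least the real 25 macrophage-like genes (highest other 136), 25 at least the real 3 genes of the other classes (highest other 587) and 5 at least the real 10 lists (highest other 13). The split with 136 and 587 genes parts the libraries 1 from the libraries 2, with both macrophage-poor libraries on 1 side, and points to a further structure of the samples. With a term for those 2 libraries in place of the set, the real split called 6 macrophage-like genes and 1 of the other classes.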
